A study of Drosophila melanogaster with 3 samples.

How the data were processed

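Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster prepupae of pooled sex from a transgenic line carrying CG4318 fused to enhanced GFP. Per the labels, an antibody against GFP was used, chromatin was fragmented by sonication, and the 3 samples are 3 biological replicates of 1 group. The labels give the age as 48 days, which no prepupa reaches; the stage label was used and the age was not. The labels name a possible control experiment, which was not analysed here.

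The deposited files are peak lists in narrowPeak format, in builds dm6 and dm3. Per the descriptions deposited with the samples, each replicate's candidate list was derived from that replicate's alignment and 1 further file whose role is not stated. The pooled candidate list was derived from the 3 alignments and a further file, and the reproducible list from the 3 replicate lists and the pooled list by thresholding the irreproducible discovery rate (IDR). The aligner, the peak caller and their versions are not given in the sources used here. The strength of a region is the deposited signal score, as the authors' peak caller gave it, on a scale that is not stated. It was used only to rank or describe regions within 1 list. The deposited −log10 q-value was read only to describe the lists, since 75.9% of reproducible peaks share its highest value of 3.89. Each list also gives the summit position. The files hold no read counts, so the sequencing depth is unknown, and intervals cover counting error over peaks only. The score column that could hold a scaled IDR value is 0 throughout, so a stricter IDR threshold was not run.

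The 6 arms that carry dm6 peaks were compared with the Release 6 reference assembly, and every region lay within the arm's length. Gene models were those of Ensembl release 115 (BDGP6 annotation 54). Coordinates are 1-based dm6 positions. No dm3 sequence or annotation was used, so the dm3 lists entered only counts and overlaps.

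Replicate support was the share of the 5056 reproducible peaks overlapped by at least 1 bp by a replicate's 5056 strongest regions, called its top list below. Chance values came from 100 random placements on the same arm. Spearman correlations were computed across peaks, which are not independent replicates, so no p-value is given. Summits within 500 bp of a transcription start site (TSS) of a protein-coding gene were called promoter summits. The other summits were assigned to 5′ UTR, 3′ UTR, coding exon, other exon, intron or intergenic sequence, in that order. Shares were compared with the shares of bases by 2-sided exact binomial tests, with Benjamini-Hochberg adjustment over 7 features or 7 arms. Signal scores at promoters and elsewhere were compared by a 2-sided permutation test with 100000 resamples. A gene was called bound when a reproducible summit lay within 500 bp of any of its TSSs. The 18 gene lists were tested by 2-sided Fisher's exact tests against the other protein-coding genes of the same arms, with Benjamini-Hochberg adjustment. Older gene symbols were accepted only where they belonged to 1 gene, which left 3 listed symbols unmatched; this rule replaced a looser one after wrong matches had been seen. Motifs (16 consensus sequences) and 6-mers were counted on either strand in 101 bp windows at summits and in windows centred 400 bp to each side, with Fisher's exact tests and the same adjustment. The threshold was an adjusted p of 0.05, and intervals are 95% Wilson intervals. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

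The tests, gene lists, motifs and the rule for named genes were fixed before the data were examined. The rule names CG4318, the gene with the TSS nearest to each of the 15 strongest reproducible peaks, up to 3 members of each list with the strongest promoter peak, every motif past the threshold, and the 5 highest and 3 lowest 6-mers by odds ratio. Alternatives covered overlap criteria, list lengths, builds, TSS windows, expectations, window sizes and the omission of each replicate. Comparisons with GC-matched positions (2 random positions per summit on the same arm with the same GC count in 101 bp, over 500 bp from any reproducible summit), with genes of the same number of TSSs, with 1 TSS per gene, with each promoter summit counted once by its nearest TSS and with single replicates were added after the data were seen.

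The 6-mer, gene list, overlap, promoter share and signal tests were tried on simulated data; the motif, divergent promoter, arm, other feature and gene-span tests were not. All 3 planted 6-mers among 2080 were recovered, 1 unrelated 6-mer was called, and 0 were called with nothing planted. The overlap count was right in 800 of 800 simulated regions, and the promoter test called 200 of 200 sets at 15% against 12% and 8 of 200 at the expected share. For gene lists, 184 of 200 simulated lists of 30 genes with 40% bound were recovered, against 79 of 200 lists of 10 genes, and 11 of 3200 lists at the background share were called.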

Results

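The data describe where the GFP-tagged product of CG4318, a single-exon gene on the X chromosome, was found on chromatin in whole prepupae, the stage at which the larval body begins to be rebuilt into the adult. There were 3 biological replicates of 1 group, so the comparisons are between replicates and between parts of the genome. Each replicate's list and the pooled list hold 30000 candidate regions, and the reproducible list holds 5056 peaks in dm6. The depth of the libraries is unknown. The reproducible peaks were the 5056 strongest regions of the pooled list, with signal scores from 108.7 to 2606 and a median of 193.3. Membership of a single peak therefore followed its pooled signal score, and not its presence in each replicate. In dm3 the reproducible list holds 4857 peaks, and merging overlapping dm6 peaks left 4767.

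The strongest peaks lay at or near genes of varied function, and 63 of the 100 strongest summits were at promoters. The highest signal score, 2606, belonged to a peak on X with its summit at position 2703891, 39 bp upstream of the TSS of Ugalt, a UDP-galactose transporter. It was followed by a peak on 3L at 19590623, 99 bp upstream of CG14100, with a score of 2558. The third, with a score of 2306, was on 2L at 481063 in an intron of ush, with the TSS of cbt 1375 bp away. The fourth, on 3L at 14759519, lay in an intron of Trl, which encodes GAGA factor, 1530 bp from its nearest TSS, with a score of 2163. The fifth lay in an intron shared by the HMG-box genes HmgD and HmgZ on 2R at 21703391, with a score of 2137. Next in rank were peaks nearest to CG4004, CG31145, PNPase, CG4496 and CG11050, with scores from 1962 down to 1894. The peak nearest to CG4004 was in a non-coding exon 5000 bp from that gene's TSS, and those at CG31145 and PNPase were promoter peaks. The 5 that completed the 15 strongest lay nearest to Tcs5, mRpL41, CG13323, Chro and CG16753. Among them, the peaks at Tcs5, mRpL41 (a mitochondrial ribosomal protein) and Chro (the chromatin protein Chromator) were at promoters, whereas the peak nearest to CG13323 was intergenic, 11920 bp from its TSS, and that nearest to CG16753 was in an intron of CG32486. All 15 were in the top list of each of the 3 replicates, at ranks from 1 to 22.

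At the CG4318 gene itself (X, 13153461 to 13154924, minus strand, FBgn0030455) no region was listed. None of the 30000 candidates of any replicate or of the pooled list overlapped the gene. The nearest reproducible summit, at 13143313, was 10148 bp away with a signal score of 553.

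The replicates were compared to ask how far they listed the same sites. Replicate 1's top list overlapped 84.6% of reproducible peaks (95% interval 83.6 to 85.6), replicate 2's 84.2% (83.2 to 85.2) and replicate 3's 73.3% (72.0 to 74.5), a mean of 80.7% ± 6.44 (SD, n = 3). Random placement gave 2.63%, 2.67% and 2.65%. The reproducible list was derived from these same replicates, so support far above random placement was largely built in. All 3 top lists held 2863 peaks, or 56.6% (55.3 to 58.0), and 59 peaks were in none. Replicate 3 stood apart: 853 peaks were in the top lists of replicates 1 and 2 but not 3, against 309 missing only from replicate 2 and 355 only from replicate 1. Top lists of replicates 1 and 2 overlapped by 80.1%, those of 1 and 3 by 62.3% and those of 2 and 3 by 64.1%, with chance values of 2.67%, 2.61% and 2.74%. Signal scores were also compared among reproducible peaks, which were the strongest regions of the pooled list. For regions listed by both replicates, Spearman correlations were 0.78 for replicates 1 and 2, 0.74 for 1 and 3 and 0.80 for 2 and 3.

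**Figure D1:**
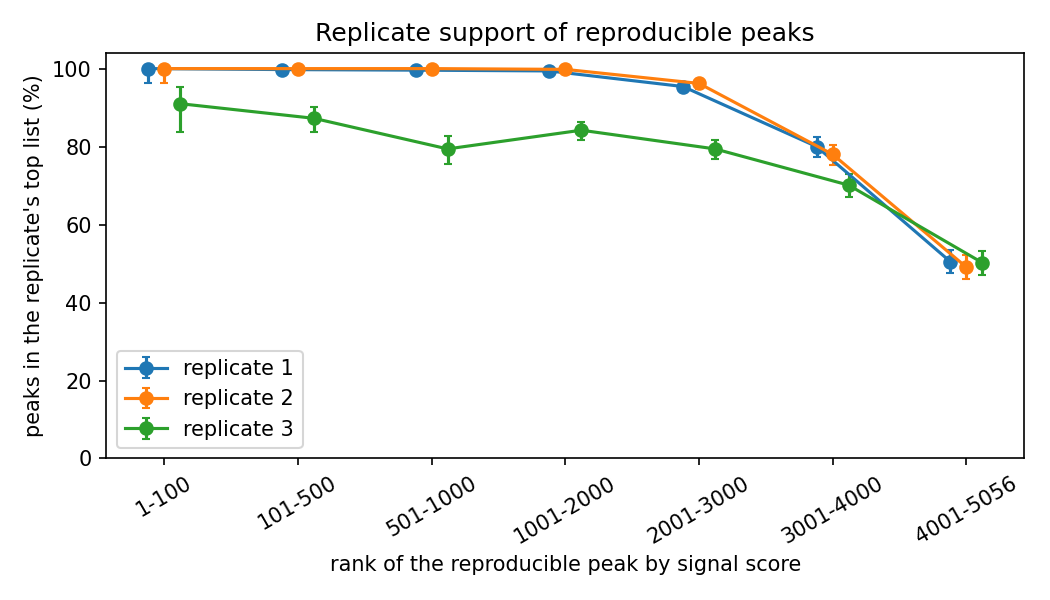
Percent of reproducible peaks (y axis) found in the top list of each replicate, by rank of the peak in signal score (x axis), with 95% Wilson intervals as bars. Among ranks 501 to 1000, 99.6% and 100% of peaks were in the top lists of replicates 1 and 2 and 79.4% in that of replicate 3.

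The peaks missing from replicate 3 included strong promoter sites. No candidate of any rank in replicate 3 overlapped 827 reproducible peaks, or 16.4% (15.4 to 17.4), while replicates 1 and 2 listed regions at 99.6% and 99.8% of the peaks. Of the 827, 40% were at promoters, against 20.6% of the peaks listed in replicate 3 (odds ratio 2.57, Fisher's exact test p = 3.49e-30, chosen after the data were seen). Among the 100 strongest peaks and the next 400, only 9 and 51 were absent. There the promoter share was 77.8% of absent against 61.5% of present peaks, and 49.0% against 43.3%. Neither difference passed the threshold (Fisher's exact test p = 0.478 and 0.454). Over ranks 1 to 1000 the odds ratio was 1.89 (Fisher's exact test p = 0.000232). The strongest absent peaks were nearest to CenG1A, CG3552, GstE13, Lamtor3 and eEF1gamma, named after their values were seen. Their ranks in the reproducible list were 28, 43, 44, 51 and 57. The peak nearest to eEF1gamma was intergenic, 5721 bp from its TSS, and the others were at promoters.

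Reproducible summits were found at promoters and in introns more often than the bases of these predict, and were nearly absent from coding sequence. Promoters held 1204 of 5056 summits, or 23.8% (22.7 to 25), against 11.5% of bases (exact binomial p = 6.66e-133). Introns held 52.7% against 39.9%, with an adjusted p of 1.21e-74. Coding exons held 3 summits, or 0.0593%, against 13.3% of bases, with an adjusted p of 4.32e-305. The 3′ UTRs held 0.435% against 5.17%, 5′ UTRs 0.336% against 0.794% and intergenic sequence 20.7% against 27.7%, with adjusted p of 5.79e-84, 7.67e-05 and 3.38e-30. Other exons, at 1.94% against 1.60%, did not pass the threshold (exact test, adjusted p = 0.0565). Against GC-matched positions, promoters held 23.8% against 10.8% and coding exons 0.0593% against 2.00%. In that comparison the difference in 5′ UTRs no longer passed (exact test, adjusted p = 0.0502), and other exons passed at 1.94% against 1.11% (adjusted p = 7.25e-05).

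**Figure D2:**
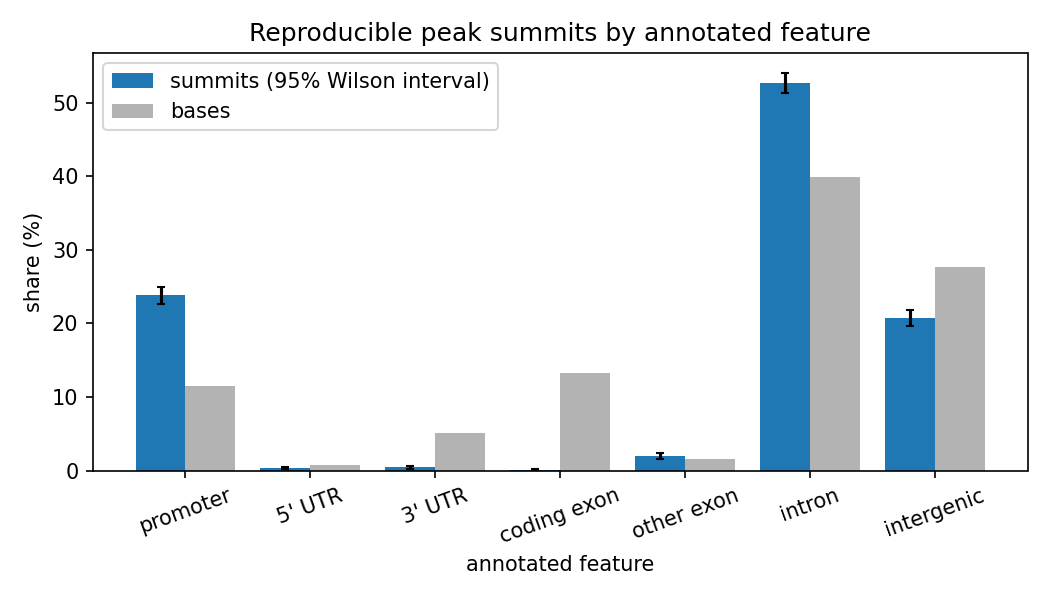
Percent of reproducible summits (blue bars, with 95% Wilson intervals) and of bases (grey bars) in each annotated feature class. Promoters held 23.8% of summits and 11.5% of bases, and coding exons 0.0593% and 13.3%.

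Promoter peaks were also stronger. Their median signal score was 242.8 against 181.9 elsewhere, a difference of 60.9 (permutation p = 1e-05, the smallest the resamples can give). The share of summits at promoters was 63.0% (53.2 to 71.8) among the 100 strongest peaks and 17.1% (15 to 19.5) among ranks 4001 to 5056. A TSS on the opposite strand lay upstream within 500 bp of 519 of 1616 bound TSSs, or 32.1%, and of 21.7% of unbound TSSs (odds ratio 1.71, Fisher's exact test p = 2.27e-20). In this count 1 summit can mark both TSSs of a pair. When each promoter summit was counted once by its nearest TSS, 218 of 1204, or 18.1%, faced a divergent TSS against 14.9% of promoter bases (odds ratio 1.27, exact binomial p = 0.00207, added after the data were seen). With 250 bp between the TSSs the odds ratio was 1.17 and did not pass the threshold (Fisher's exact test p = 0.0564).

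Peaks were unevenly spread over the chromosome arms. X held 1020 peaks, or 20.2% (19.1 to 21.3), against 17.1% of bases, and 3L held 23.3% against 20.4%, with adjusted p of 4.40e-08 and 7.04e-07. Arm 2R held fewer than its bases predict, 15.7% against 18.4%, with an adjusted p of 7.04e-07. Chromosome 4 held 12 peaks, 0.237% against 0.971% of bases (exact test, adjusted p = 1.48e-09), and Y held 0 against 2.49%. The pooled candidate list also held 0 regions on Y, so no reproducible peak could lie there. Shares on 2L and 3R did not pass the threshold (exact test, adjusted p = 0.0891 and 0.111). The expected shares counted the bases of Y, which lowers the expectation of every other arm. Against protein-coding TSSs per arm, 3R passed as lower, at 22.4% against 23.7% (exact test, adjusted p = 0.0433). X, 3L, 2R and chromosome 4 kept their direction and passed there too, and 2L did not pass. Against the other pooled candidates, 3L no longer passed (23.3% against 22.8%), 2R lay above expectation without passing (15.7% against 14.9%, exact test, adjusted p = 0.115), and 2L (18.1% against 20.4%) and 3R (22.4% against 24.4%) passed as lower, with adjusted p of 7.68e-05 and 0.00139. In replicate 3's top list alone the X share was 18.1% with an adjusted p of 0.0819, and 2L passed as higher, at 18.6% with an adjusted p of 0.00904.

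Of 13945 protein-coding genes, 1311, or 9.40%, had a promoter peak, and 5 of the 18 gene lists differed from the other genes. Genes of the ecdysone response, the steroid hormone pathway that drives metamorphosis, were bound in 10 of 34 cases, or 29.4% (16.8 to 46.2), against 9.35% of other genes (odds ratio 4.04, Fisher's exact test, adjusted p = 0.00736). The strongest were at Ldh (lactate dehydrogenase, score 766), the nuclear receptor gene Eip75B (score 581, 15 bp from a TSS on 3L at 17999806) and Eip63E (score 327). The circadian list, which also covers early hormone-coupled bHLH and bZIP genes, had 5 of 10 genes bound (exact test, adjusted p = 0.00736). It was led by the kinase gene sgg (score 811), the cryptochrome gene cry (465) and dco (206). Its unbound members were per, tim, Clk, cyc and cwo, and its bound member vri is also in the ecdysone response list. Glycolysis genes were bound in 5 of 12 cases (exact test, adjusted p = 0.0148), among them Gapdh2 (score 770), Ldh and Eno (enolase, score 693). Core cell cycle genes were bound in 7 of 27 cases (exact test, adjusted p = 0.0380), led by CycE (score 424), Dp (359) and Cdk1 (217). Cuticle genes were bound in 1 of 111 cases, 0.901% against 9.47% of other genes (exact test, adjusted p = 0.00736), the exception being Cpr50Ca. With a TSS window of 250 bp, ecdysone response genes no longer passed, at 5 of 34 (exact test, adjusted p = 0.233). Neither did circadian genes, at 2 of 10, and core cell cycle genes, at 2 of 27 (exact tests, adjusted p = 0.306 and 0.816). With 1000 bp cuticle genes no longer passed, at 6 of 111 (exact test, adjusted p = 0.0826). With only the peaks in all 3 top lists, ecdysone response genes were bound in 3 of 34 cases (8.82%, exact test, adjusted p = 0.641) and core cell cycle genes in 0 of 27, below the 5.37% of other genes (adjusted p = 0.641), and only the circadian list passed (4 of 10, adjusted p = 0.0239). Promoter peaks of Eip75B, Gapdh2, Eno, CycE, Dp and Cdk1 had no candidate in replicate 3. Binding was more frequent in genes with more TSSs, from 5.82% of genes with 1 TSS to 48.9% of those with 5 or more. When genes were compared only with genes of like TSS number, 0 of the 18 lists passed. The lowest adjusted p, 0.0715 (permutation test), was shared by cuticle and mitochondrial ribosomal protein genes, the latter with 12 bound and 4.88 expected. The bound and expected numbers were then 10 and 6.38 for ecdysone response, 5 and 1.82 for circadian, 5 and 2.79 for glycolysis, 7 and 3.50 for core cell cycle and 1 and 7.43 for cuticle genes (permutation test, adjusted p = 0.318, 0.171, 0.346, 0.259 and 0.0715).

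**Figure D3:**
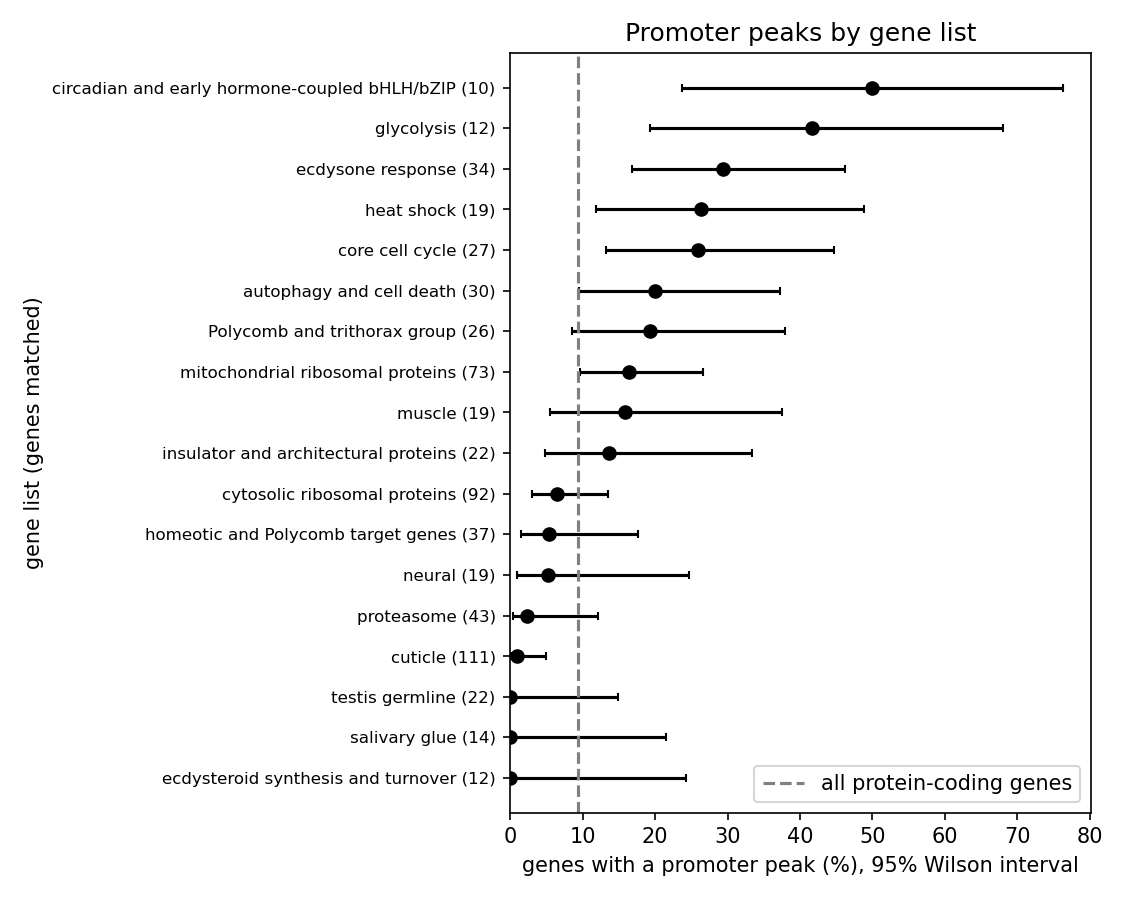
Percent of genes with a promoter peak (x axis) in each of the 18 gene lists, with 95% Wilson intervals; the dashed line is the share of all protein-coding genes, 9.40%. Circadian genes stood at 50%, glycolysis genes at 41.7% and cuticle genes at 0.901%.

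The other 13 lists did not pass the threshold. Heat shock genes were bound in 5 of 19 cases (exact test, adjusted p = 0.0831), with a strong peak 160 bp upstream of Hsp27 (score 1619) and weaker ones at Hsp26 (339) and Hsc70-4 (292). With a TSS window of 250 bp this list passed, at 26.3% and an adjusted p of 0.0273, and with 1000 bp at 42.1% and 0.00894. With only the peaks in all 3 top lists, 1 of 19 was bound, 5.26% against 5.36% of other genes. Mitochondrial ribosomal protein genes were bound in 12 of 73 cases (exact test, adjusted p = 0.148), including mRpL41 (score 1788), mRpS10 (1491) and mRpS23 (1438, absent from replicate 3), and cytosolic ribosomal protein genes in 6 of 92 (adjusted p = 0.606), led by RpS20 (372), RpL8 (252) and RpL23 (246). A summit within 500 bp of TSSs of several genes marks each of them. The mRpS23 peak is the same as that nearest to CenG1A, and Cdk1 and mRpS7 share a peak. Genes of autophagy and cell death were bound in 6 of 30 cases (exact test, adjusted p = 0.147), led by Atg17 (602), Atg2 (515) and the pro-apoptotic gene hid (449). Polycomb and trithorax group genes were bound in 5 of 26 cases (exact test, adjusted p = 0.182), with peaks at ph-p (1373), brm (1078) and E(z) (554). Insulator protein genes were bound in 3 of 22 cases, at Chro (1747), Trl (601) and BEAF-32 (153), and muscle genes in 3 of 19, at sls (373), Act87E (183) and Tm1 (153). Homeotic and Polycomb target genes were bound in 2 of 37 cases, at tin (297) and Poxn (153). Neural genes were bound in 1 of 19, at elav (735), and proteasome genes in 1 of 43, at Rpn5 (245). Of these promoter peaks, those of RpS20, Hsp26, BEAF-32, tin and Tm1 also had no candidate in replicate 3. That of Hsc70-4 had none in replicate 1. No promoter peak was found at the 12 genes of ecdysteroid synthesis, the 14 salivary glue genes or the 22 testis germline genes, for which 0 bound genes allow upper bounds of 24.2%, 21.5% and 14.9%.

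Summits were rich in A and T. GC content in the window at the summit was 30.9% ± 7.12 (SD over 5056 peaks), against 44.5% ± 6.92 in windows 200 bp away and 42.2% over the arms, and it was lower at the summit in 90.2% of peaks. It was 31.3%, 31.4% and 33.1% in the top lists of replicates 1, 2 and 3, and 37.7% in pooled candidates outside the reproducible peaks.

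**Figure D4:**
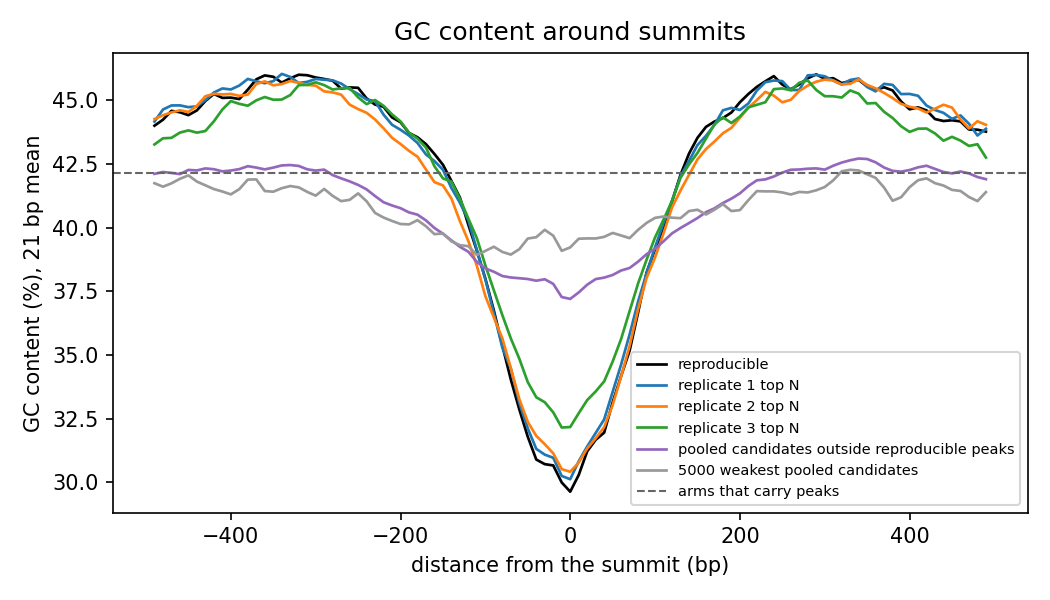
Mean GC content (percent, 21 bp running mean) against distance from the summit (bp) for reproducible peaks, each replicate's top list, other pooled candidates and the 5000 weakest pooled candidates; the dashed line is the 42.2% of the arms. Windows at the summit averaged 30.9% in reproducible peaks and 39.5% in the weakest candidates.

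Of the 16 motifs, 9 differed between summits and flanks 400 bp away. The TATA box was found at 7.58% of summits against 2.91% of flanks (odds ratio 2.74, Fisher's exact test, adjusted p = 1.19e-35), and the su(Hw) site at 9 summits against 2 of 10112 flanks (adjusted p = 0.00547). The GAGA motif was less frequent, at 0.791% against 3.52% (exact test, adjusted p = 1.16e-26), as were the E-box (0.435% against 1.19%), core promoter motif 7 (2.25% against 3.05%), Zelda (0.297% against 0.643%), ftz-f1 (0.119% against 0.316%), AP-1 (0.554% against 0.900%) and CRE (0.0593% against 0.247%), with adjusted p from 1.29e-05 to 0.0434. Of 2080 6-mers, 614 were more and 1136 less frequent at summits. The highest odds ratios were 5.37 for ATATTA, 5.02 for TTTAAA, 4.84 for TATTAA, 4.56 for AATATA and 4.55 for TTAAAA, and the lowest were 0.0598 for CCCGGC, 0.0540 for CGGCCG and 0.0509 for CCGGCC. Against GC-matched positions, 0 motifs passed (TATA box 7.58% against 7.12%, exact test, adjusted p = 0.568), and 301 6-mers differed, 173 of them more frequent at summits.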

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

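The tests of the weakest candidates, of AT-rich stretches in its present form and of the strong peaks absent from replicate 3 were chosen after those results had been seen; the bounds of the other tests of explanations were written before their values were read. With 3 samples in 1 group, no sample was tested as an outlier and no groups were compared.

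Among pooled candidates outside the reproducible peaks, 86 of 24207 lay in the top lists of 2 or more replicates, and 3 of them in all 3. These counts were not set against a chance value, and the regions lie outside the list used for the results. In dm3, 4 reproducible peaks lay on scaffolds outside the 7 arms, with 2 on 3LHet, 1 on 2RHet and 1 on XHet, and 476 pooled candidates lay on such scaffolds.

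Replicate 3 stood apart from replicates 1 and 2, and its regions were narrower, at most 389 bp against 767 and 763 bp, but with its regions widened by 200 bp on each side 16.1% of reproducible peaks still had no candidate, against 16.4% before. Weaker enrichment as the whole cause is argued against by the 1000 strongest peaks, 16.3% of which had no candidate of any rank. As part of the cause it stays open, since the share was 9% in the 100 strongest, 12.8% in the next 400 and 20.6% in ranks 501 to 1000. A top list that reaches into background would also hold few promoter regions of its own. Of the regions in replicate 3's top list alone, 8.23% were at promoters and 35.3% intergenic. In the top lists of replicates 1 and 2 alone, 30.7% and 34.5% were at promoters and 21.5% and 15.7% intergenic. A separate set of sites of like sequence is argued against by the regions in its top list alone, where GC content 200 bp away exceeded that at the summit by 5.80 percentage points, against 13.6 in reproducible peaks. The test of weaker enrichment replaced one written earlier, which found 79.4% of ranks 501 to 1000 in its top list, between its bounds of 75% and 90%. Differences in how its list was made, or in the age or handling of the animals, stay open, since the labels are alike for all 3.

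Replicate 3 also listed fewer X regions, 13.1% of its candidates against 19.0% and 17.6% in replicates 1 and 2. At reproducible peaks, lower recovery of X regions is argued against, because 73.8% of X peaks were in its top list and 73.1% of the autosomal ones. These are the strongest regions of a pool that includes replicate 3, so recovery of weaker X regions was not tested. Among its top regions that overlap reproducible peaks, 20.3% were on X, close to the 20.2% of the reproducible list, so the difference lay among its other regions. Why its other regions held fewer on X was not tested.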

How the results depend on the processing

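Comparisons with GC-matched positions, within TSS number, with 1 TSS per gene, with each promoter summit counted once and with single replicates were added after the data were seen. The promoter share and the signal difference at promoters kept their direction and their side of the threshold in every alternative run. The count of feature classes past the threshold was 6 in every alternative, and that of arms 4 to 6. Counted over single gene lists, motifs, features, arms, named 6-mers and named promoter peaks, 359 results kept their call, counted so whatever their direction when past the threshold in neither case, 87 became weaker, 7 stronger and 10 reversed. Depth is unknown and limits every count, and no stricter IDR threshold was run, since the score column is 0 throughout. The arm test was not run in dm3, for which no arm lengths were used. No paired analysis was possible because there is 1 group. Except where a construction is named, the cause was not tested. Mean replicate support was 69.5% with a reciprocal overlap of 50% and 92.2% with top lists of 10112 regions. Peaks in all top lists were 40.3% with that overlap, 48.1% with summits within 100 bp, 77.1% with the longer lists, and 62.7% to 73.5% with each replicate left out, since fewer lists must then hold a peak. Mean pair overlap was 57.9% with the longer lists and 62.3% to 80.1% without each replicate, the highest without replicate 3. The rank correlation was 0.74 to 0.80 without each replicate. The count of gene lists past the threshold was 5, and became 3 with a 250 bp window, 1 against genes with a candidate at a TSS, 0 with the 2528 strongest peaks, 1 with peaks in all 3 top lists and 0 within TSS number, with fewer peaks or genes entering some of these. The lists that passed with 250 bp were glycolysis, cuticle and heat shock, the last of which had not passed before. Odds ratios did not always fall with the calls: against genes with a candidate they were 4.67 for ecdysone response, 6.99 for glycolysis and 4.90 for core cell cycle, and glycolysis had 7.14 with the 2528 strongest peaks. In peaks of all 3 top lists, 0% of core cell cycle genes were bound, below the other genes (exact test, adjusted p = 0.641). In the regions common to replicates 1 and 2 the count was 5. The divergent promoter odds ratio was 1.17 at 250 bp and 1.27 with each summit counted once. Fixed motifs past the threshold numbered 9, and became 4 for promoter summits against unbound promoters, 2 within 25 bp of the summit and 0 against GC-matched positions. Within 100 bp of the summit DRE passed, at 0.653% against 0.287% (exact test, adjusted p = 0.00438). Core promoter motif 7, Zelda and CRE no longer passed there. In the promoter comparison the BEAF-32 motif was at 11.8% and M1BP at 0%, both below the controls and past the threshold (exact tests, adjusted p = 0.0241 and 0.0294). Against GC-matched positions GAGA (0.791%), core promoter motif 7 (2.25%), Zelda (0.297%), AP-1 (0.554%) and CRE (0.0593%) lay above the controls without passing. For 6-mers the count was 1750, and became 811 in the promoter comparison, 301 against GC-matched positions and 10302 with 8-mers, of which more were tested. Against the other pooled candidates 2L, at 18.1%, lay below and 2R, at 15.7%, above expectation.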

Other observations

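The tests in this part were chosen after the peaks had been seen; for AT content alone the bounds were written before the value was read, and the test of an AT-rich stretch was changed after a first version had left out loci near the peaks.

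Counting summits anywhere within a gene or 2000 bp around it, rather than at promoters, gave a partly different picture of the gene lists. Polycomb and trithorax group genes held 36 summits where their length predicts 13.2, a ratio of 2.72 (exact binomial test, adjusted p = 1.03e-06), and were past the threshold against GC-matched positions too (odds ratio 6.04, Fisher's exact test, adjusted p = 7.22e-08). Ecdysone response genes held 102 summits against 42.7 predicted (exact test, adjusted p = 1.88e-13, and 1.32e-06 against GC-matched positions), and glycolysis genes 14 against 3.66 (adjusted p = 0.000133 and 0.000208). Neural genes held 3 summits against 25.7 predicted (exact test, adjusted p = 4.35e-07 and 5.40e-07). Mitochondrial ribosomal protein genes held 24 against 14.4 (exact tests, adjusted p = 0.0432 and 0.00220). Core cell cycle genes (20 against 9.75) and circadian genes (18 against 8.42) passed by length (exact test, adjusted p = 0.00966 each) but not against GC-matched positions (0.0875 and 0.434). Cuticle genes, seldom bound at promoters, passed neither test, with 11 against 19.1 (exact tests, adjusted p = 0.131 and 0.195). Both tests count every summit as an independent draw, although summits clustered within genes. In the ecdysone response list Hr4 held 11 summits, Eip75B 9 and Eip74EF 8. The p-values therefore do not measure the spread over the genes of a list. GC-matched positions also lay over 500 bp from any reproducible summit, which by construction lowers their share in genes dense in summits. Long genes differed in how many summits they held: kirre held the most, 24 where length predicts 14.9, and Ten-a 8 against 11.0, while Snoo and sbb held 20 each where length predicts 3.52 and 2.99, shn held 19 against 2.21, and Mnt held 12 against 1.13. Annotated transposable elements held 12 summits, 0.237% against 5.94% of bases (exact binomial p = 1.63e-113); how reads from repeats were treated is not given in the sources used here.

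The AT-rich summits may reflect the sites themselves or the way regions are called. To ask whether an AT-rich stretch between GC-richer flanks is enough to be called, loci were drawn from whole arms and matched to the summits in both. Of these, 15.7% (14.8 to 16.8) lay within 200 bp of a pooled candidate summit, against 8.94% of random loci. Such stretches were called more often but mostly were not. The pooled list holds only 30000 regions, and such stretches were not counted over the genome. The test therefore cannot decide whether a stretch is enough. A bias common to every called region is argued against by the 5000 weakest candidates, where GC content 200 bp away exceeded that at the summit by 1.10 percentage points, against 13.6 in reproducible peaks. AT content alone would leave few 6-mers different from GC-matched positions, but 14.5% passed the threshold. The GC-matched positions also differed in feature class, with 8.81% in 3′ UTRs against 0.435% of summits. This test therefore cannot tell a sequence preference from a difference in location. A bias that acts only on strongly enriched fragments, such as in amplification, was not tested and stays open.

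A hypothesis from the same comparison is a preference for sequences around CAGTGC and CACTGA. CAGTGC was at 5.89% of summits and 2.14% of GC-matched positions (odds ratio 2.87, exact test, adjusted p = 5.53e-28), and CACTGA at 6.49% and 2.98% (odds ratio 2.26, adjusted p = 3.04e-20). The 8-mer CACTGAGA was at 1.66% of summits and 0.168% of flanks. These were picked because they ranked high, and no independent peak set was used to test them. Between peaks absent from and present in replicate 3, 0 of 2080 6-mers passed the threshold by Fisher's exact test, with 129 at an unadjusted p under 0.05.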
